A study of Danio rerio with 16 samples.

How the data were processed

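The series holds 16 single-channel Agilent gene expression arrays of total RNA from the hypothalamus of adult female zebrafish. The groups were taken from the sample titles, which name Control (5 arrays), Medium (5) or High (6), with the number in the title naming each array. High 13 is labelled Cy5, while its file holds 1 channel, the green one, like the other 15, and the labels' protocol is the 1-colour Cy3 procedure; it was used like the others. The slide and the position on it came from the array files, with 4 slides of 4 arrays.

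Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.1.1 under the 1-colour protocol, which subtracts background and detrends within an array and does no scaling between arrays. Per the file headers, the processed signal is an intensity on a linear scale, and each spot has a mark for being well above background, saturated or an outlier. The authors also deposited a table of log2 values for the same arrays. Each of its columns equalled log2 of the processed signal of its own array to within rounding, so its scale, centring and direction are known and it was not scaled between arrays. Its medians per array were 6.27 for Medium 8, 6.62 for Medium 4, 7.16 for Medium 10, 6.64 for Medium 22 and 6.59 for Medium 33. In Control they were 6.88 (Control 7), 6.68 (Control 11), 7.06 (Control 16), 7.02 (Control 31) and 6.90 (Control 26), and in High 6.67 (High 2), 6.74 (High 13), 6.65 (High 12), 7.19 (High 24), 6.73 (High 18) and 6.66 (High 32).

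Each array has 45220 spots, 43803 of them not controls, for 43603 distinct probes. Control spots were left out, and spots marked as outliers were set to missing (13 to 146 per array and 1256 on High 18). The values analysed were log2 of the processed signal minus the array's 75th percentile. The 50 probes with 5 spots each were averaged. Probes well above background on at least 5 of the 16 arrays were kept, 36640 in all. Probe accessions in the files were matched without versions to the RefSeq gene table of the GRCz12tu assembly, which gave a current symbol to 25978 probes (13373 symbols) and to 23101 of the kept probes. The array design is annotated on an older assembly, so no coordinates are given. A gene was represented by its brightest kept probe (12224 genes), and places where the probes of a named gene differ in sign are stated. A probe not well above background on all arrays of a group gives only a bound: the mean of the bright group over the mean, in the dim group, of the higher of the probe's own value and the lowest value above background on that array.

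One linear model over the 3 groups and all 16 arrays was fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over the kept probes of each comparison with a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 over 11901 genes, leaving out 323 genes with an outlier spot, and adjusted over the 31 lists of each comparison. An estimated correlation and fry were run beside it. fry's directional test asks whether a list's genes move on balance one way and its mixed test whether they change in either direction, and neither sets the list against other genes. The lists cover GABA, glutamate, dopamine and peptide signalling, steroid and stress responses, metabolism, the clock, and markers of other cell types and neighbouring tissues. They were fixed before the data were examined, as were the comparisons, the main model, the alternatives not named below as later ones, and the rule for named genes.

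By that rule, the text names for Medium and High against Control up to 5 genes of smallest p in each direction among those with a gene symbol, up to 3 members of smallest p in each list past its camera test, one member of some other lists, and some genes always (gad1b, gad2, slc6a1b, th, slc6a3, gnrh3, kiss2, cyp19a1b, esr2a, pomca, npy, avp and oxt), and for High against Medium only the 5 per direction. Some genes that the rule covers are not reported here and were left out of the screen for outlying arrays, while they stayed in all tests. Genes outside it are said to be chosen after their values were seen.

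The model was tested on simulated data with 200 of 36640 probes changed. For Medium against Control it recovered 44% of probes changed by a log2 of 1 and 82% of those changed by 2, with 3.05% of calls false. For High against Control it recovered 51% and 86%, with 6.80% false. The list that was shifted in the simulation was called in both, and 0 other lists were. The simulated noise was independent between probes, whereas correlation within the real lists was estimated at up to 0.57. The simulation therefore does not show how often camera calls a list falsely in these arrays.

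Other settings tried were slide as a block, the number in the sample description as a block, normexp background correction, quantile normalization, the deposited log2 table, other filters, array weights, a trended and robust variance model, 1 probe per gene, only the 2 groups compared, and leaving out each array in turn. The files hold the median and not the mean spot intensity, so normexp used the median. Settings added after seeing the data were normexp without spots of extreme local background, Control 7 and Control 31 averaged as 1 array, and the mean level of the erythrocyte or of the midbrain and hindbrain list as a covariate. In the text, unscaled values are those of the deposited table, whose median difference over all probes was -0.25 for Medium against Control, -0.15 for High against Control and 0.098 for High against Medium. Gene names, positions and doses that no source used here gives are not reported.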

Results

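Gene expression was measured in the hypothalamus of adult female zebrafish (Danio rerio) after 21 days on control feed or on feed that held dieldrin. Dieldrin is a persistent organochlorine insecticide that blocks GABA-A receptors, the chloride channels through which the transmitter GABA inhibits neurons. The labels name Control, Medium and High feeds and give no concentration, and a further contaminated feed of the study was not analysed here. There were 5 Control, 5 Medium and 6 High arrays, each hybridised with 1 sample on a 1-colour Agilent array. The labels do not say whether a sample was 1 fish or a pool, or whether samples came from separate tanks, so the p-values measure only the spread between these samples. The arrays lay on 4 slides of 4, and every slide held all 3 groups. Between 73.2% (High 12) and 86.0% (High 24) of probes were well above background, and 0 spots were saturated. The first principal component held 24% of the variance and the second 13.8%.

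Values are log2 signal relative to each array's 75th percentile, differences are given as log2 ± SE from limma with the matching fold, and group levels as mean ± SD. A total of 36640 probes were tested in each comparison. The number of arrays limits the precision, and the median SE of a Medium minus Control difference was 0.23.

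The comparison of Medium with Control asks which genes differed after the intermediate feed. In Medium, genes of red blood cells stood above Control. All 16 tested members of the erythrocyte list were higher, with a median of 1.25 (camera adjusted p = 7.47e-17; adjusted p = 0.203 with an estimated correlation). The adult globin gene hbba2 was 11.7-fold higher (3.55 ± 0.84), at 1.31 ± 1.14 (SD, n = 5) in Control and 4.86 ± 0.94 (SD, n = 5) in Medium. The erythroid transcription factor gata1a was 3.60-fold higher (1.85 ± 0.37), and slc4a1a, the anion exchanger of the red cell membrane, 2.78-fold higher (1.48 ± 0.37). Among members chosen after their values were seen, the globin hbaa2 was 5.86-fold higher, alas2, which starts heme synthesis in red cells, 2.90-fold, and the membrane genes rhag and sptb both 2.49-fold. Adjusted over the list alone, 11 members passed, and 0 passed when adjusted over all probes. Globin genes are close paralogs, so a globin probe can read more than 1 of them. In slides 1 to 4 the list's median was 0.92, 0.98, 1.23 and 2.46, with 1.28 when slide was a block.

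**Figure D1:**
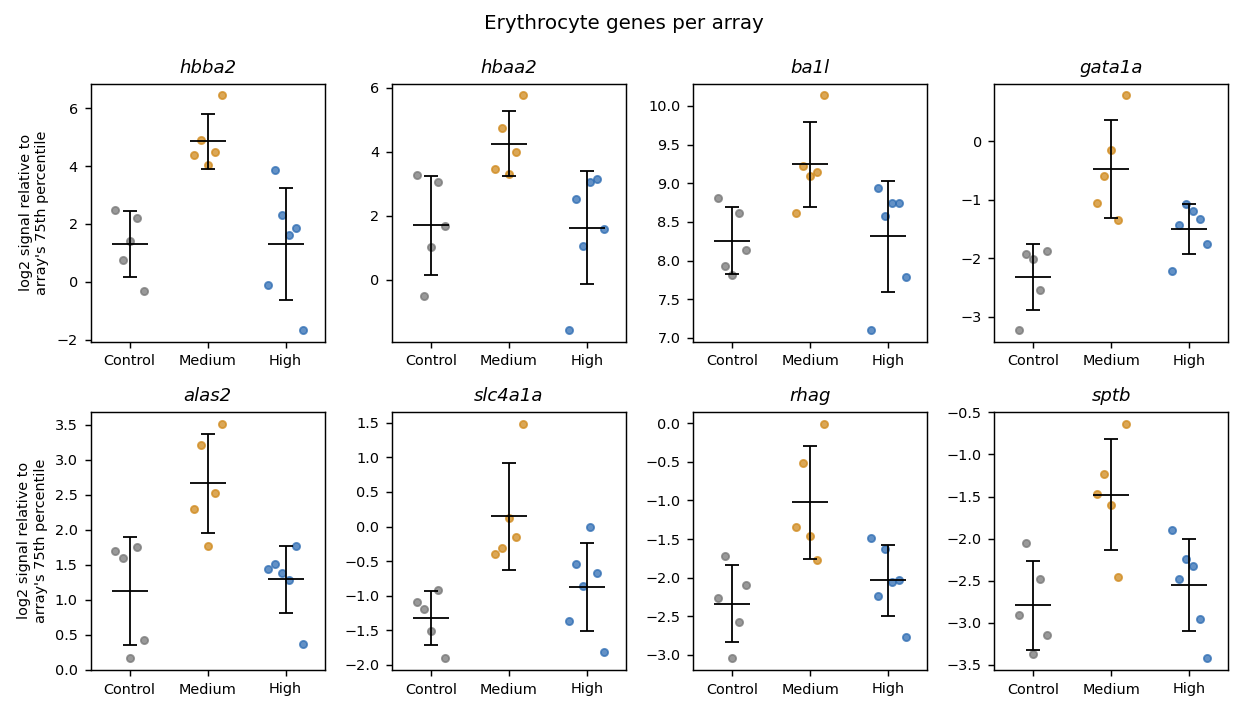
Log2 signal relative to the array's 75th percentile of 8 erythrocyte genes on each array (points) in Control (n = 5), Medium (n = 5) and High (n = 6), with the mean and SD as bars. For hbba2 the mean was 1.31 in Control, 4.86 in Medium and 1.31 in High.

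Genes of myelin-forming cells lay lower in Medium. Of the 16 oligodendrocyte genes tested, 15 were lower, with a median of -0.35 (camera adjusted p = 0.000273; adjusted p = 0.527 with an estimated correlation). The tight junction gene cldnk had -0.73 ± 0.36, and the myelin genes plp1b -0.69 ± 0.35 and mbpb -0.72 ± 0.37, although only 1 of the 3 mbpb probes had that sign. Genes that mark midbrain, thalamus and hindbrain, tissue next to the dissected region, were lower too, at a median of -0.29 over 27 genes with 18 lower (camera adjusted p = 0.00736; adjusted p = 0.527 with an estimated correlation). Examples are the transcription factors en2a (-0.80 ± 0.38), irx1a (-0.36 ± 0.17) and zic2a (-1.01 ± 0.50). Endothelial and mural genes had a median of -0.17, with 18 of 26 lower (camera adjusted p = 0.013; adjusted p = 0.527 with an estimated correlation). That call was lost with Control 7 and 31 averaged (-0.13, 0.0737) and with normexp without spots of extreme local background (-0.056, 0.0605). Their median was 0.04 under the planned normexp, which failed on 6 arrays. The glucose transporter slc2a1a had -0.44 ± 0.22, the transcription factor fli1rs -0.42 ± 0.23 and the claudin cldn5b -0.37 ± 0.23. With each array's mean midbrain and hindbrain level as a covariate, the oligodendrocyte median was -0.06 (camera adjusted p = 0.467) and the endothelial median -0.09 (0.490). With the mean erythrocyte level as a covariate, the midbrain and hindbrain median was 0.020 (0.858), the oligodendrocyte median -0.19 (0.541) and the endothelial median -0.19 (0.377). That level was higher on every Medium array (0.27 or more) than on any Control (at most -0.13) or High array (at most 0.14). In comparisons with Medium this covariate thus nearly stands for the group. Changes under it there cannot tell red cell content from any other difference of the Medium group.

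Immediate early genes, which neurons switch on within minutes of activity, were lower in 15 of 22 cases, with a median of -0.21 (camera adjusted p = 0.00846; adjusted p = 0.527 with an estimated correlation). Their members included egr1 (-0.63 ± 0.26), ier5 (-0.40 ± 0.18) and junba (-0.30 ± 0.15). The sex steroid and gonadotropin list lay higher in 20 of 26 genes, with a median of 0.20 (camera adjusted p = 0.00846; adjusted p = 0.511 with an estimated correlation). In unscaled values its median was -0.05, where that of all probes was -0.25. The receptors for gonadotropin-releasing hormone had 0.91 ± 0.38 (gnrhr3) and 1.02 ± 0.43 (gnrhr1), and the androgen receptor ar had 0.39 ± 0.17, with 3 of 5 probes of that sign. Only 1 of 5 Control arrays measured gnrhr3 above background and 2 of 5 gnrhr1. The gnrhr1 difference leans on Medium 33, at -2.37 against -5.10 to -4.69 on the other Medium arrays. With the midbrain and hindbrain covariate the steroid list had a median of 0.13 (camera adjusted p = 0.0836), and with the erythrocyte covariate 0.15 (0.377). Cytosolic ribosomal protein genes lay higher in 74 of 80 cases by a small median of 0.12 (camera adjusted p = 5.05e-07; adjusted p = 0.703 with an estimated correlation). Their median was -0.13 in unscaled values, where that of all probes was -0.25. It was -0.36 under the planned normexp background, 0.088 with the call lost (0.0605) under normexp without extreme spots, and -0.02 with the erythrocyte covariate. Among them rpl13 had 0.32 ± 0.13, rpl14 0.33 ± 0.14 and rps18 0.29 ± 0.14. Skeletal muscle genes, a possible trace of other tissue, were lower in 21 of 28 cases at a median of -0.47 (camera adjusted p = 0.0127; adjusted p = 0.656 with an estimated correlation), a call lost in unscaled values (-0.72, 0.306) and under the planned normexp (-0.059, 0.578). Of their leading members only mybphb was lower (-0.86 ± 0.31, 2 of 3 probes), while the myosins smyhc1 (1.39 ± 0.52) and myhz1.2 (1.08 ± 0.45) were higher, with 4 of 5 and 3 of 5 Control arrays above background.

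No single probe passed the limma test of Medium against Control after Benjamini-Hochberg adjustment (0 of 36640, smallest adjusted p = 0.320), and 2040 had an unadjusted p under 0.05 where chance gives 1832, 1157 of them higher. With slide as a block the counts were 0 and 2122. Of named genes, git2b, a GTPase-activating protein for Arf, was 2.17-fold higher (1.12 ± 0.20) and cox7a1, a subunit of cytochrome c oxidase, 2.21-fold (1.15 ± 0.26). For clmnb, a gene of the calmin family that was not well above background on any of the 5 Control arrays and was above it on all 5 Medium arrays, Medium was at least 2.96-fold higher. The genes with the smallest p in the other direction were glis3 (-0.99 ± 0.23), angptl1b (-1.44 ± 0.35), gnl1 (-0.79 ± 0.20), abi3a (-1.04 ± 0.27) and foxo1a (-1.10 ± 0.31), a forkhead factor of insulin signalling, with glis3 and angptl1b above background on 3 of 5 Medium arrays. The unadjusted count was 3330 without Control 11.

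In slides 1 to 4 and then with slide as a block, the list medians were -1.07, -0.24, 0.62, -0.57 and -0.47 for oligodendrocyte, -0.52, -0.26, 0.28, -0.28 and -0.31 for midbrain and hindbrain, and -0.33, -0.091, 0.14, -0.19 and -0.19 for endothelial genes. They were -0.13, -0.27, -0.43, 0.18 and -0.18 for immediate early genes, -0.0028, -0.022, 0.31, 0.17 and 0.12 for ribosomal genes, 0.43, 0.052, 0.10, 0.27 and 0.20 for the steroid list, and -0.15, -0.45, 0.30, -0.53 and -0.36 for muscle genes. With the block the steroid and muscle calls were lost, both at camera adjusted p = 0.0587. Leaving out 1 array ended the call for the steroid list (Medium 8, adjusted p = 0.160), the midbrain and hindbrain list (Control 11, 0.0905), endothelial genes (Control 7, Control 11 or Medium 22, up to 0.143), immediate early genes (Medium 10, Medium 22 or Control 16, up to 0.143) and muscle genes (Medium 10, High 18 or Control 26, up to 0.491), and for none of the erythrocyte, ribosomal and oligodendrocyte lists.

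The comparison of High with Control asks the same of the highest feed. In High, genes of the circadian clock differed from Control in both directions. The whole list had a median of -0.16 with 16 of 27 genes lower, so that camera did not call it (adjusted p = 0.238), whereas the fry test for change in either direction gave an adjusted p of 0.0296. That call was lost without any 1 of Control 7, 26 or 31, High 13, 18, 24 or 32, Medium 8 or Medium 10 (adjusted p up to 0.229), with Control 7 and 31 averaged (0.203), with the midbrain and hindbrain covariate (0.0596) and in unscaled values (0.0806). The description number as a block (0.232) and the planned normexp (0.554) ended it too. Adjusted over the list alone, 9 of 27 members passed in limma, and 0 passed when adjusted over all probes. The repressor nr1d2a was 3.12-fold lower (-1.64 ± 0.43), at 1.45 ± 0.74 (SD, n = 5) in Control and -0.19 ± 0.34 (SD, n = 6) in High. Among members chosen after their values were seen, per1b (-0.95 ± 0.30), cry1b (-0.87 ± 0.25), cry2 (-0.74 ± 0.25) and nr1d2b (-0.46 ± 0.15) were lower. The activator bmal1a (0.93 ± 0.29), its relative bmal2 (0.93 ± 0.32, above background on 2 of 5 Control and 4 of 6 High arrays), cry3a (0.88 ± 0.25) and cry3b (0.74 ± 0.23) were higher. With slide as a block 8 members passed. The count was 0 without any 1 of Control 7, Control 26, Control 31, High 13 or High 24, 2 without High 18 and 17 without Control 16, and 0 when Control 7 and Control 31, the most similar pair of arrays, were averaged.

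**Figure D2:**
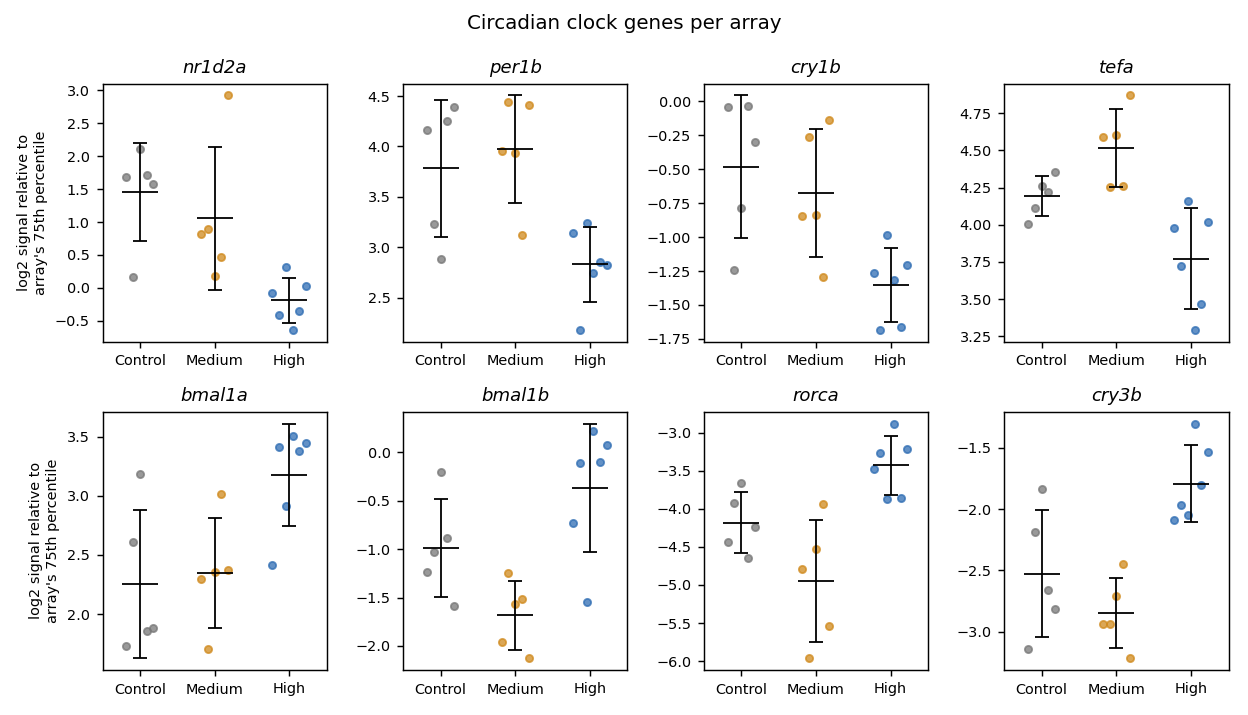
Log2 signal relative to the array's 75th percentile of 8 clock genes on each array (points) in Control (n = 5), Medium (n = 5) and High (n = 6), with the mean and SD as bars. The mean of nr1d2a was 1.45 in Control, 1.06 in Medium and -0.19 in High, and that of bmal1a was 2.25, 2.35 and 3.18.

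Cell type lists were lower in High as well. Endothelial and mural genes had a median of -0.18 with 20 of 26 lower (camera adjusted p = 0.00535; adjusted p = 0.454 with an estimated correlation), but 0.03 under the planned normexp background. Their members erg (-0.50 ± 0.19), an endothelial transcription factor, igfbp7 (-0.81 ± 0.30) and the smooth muscle actin acta2 (-0.51 ± 0.22) had the smallest p. Oligodendrocyte genes had a median of -0.28 with 14 of 16 lower (camera adjusted p = 0.00838; adjusted p = 0.928 with an estimated correlation), including mbpb (-0.71 ± 0.36), cldnk (-0.67 ± 0.34) and plp1b (-0.66 ± 0.34). Inflammation and interferon genes had a median of -0.26 with 20 of 29 lower (camera adjusted p = 0.0463; adjusted p = 0.928 with an estimated correlation). They included the immunoproteasome subunit psmb8a (-0.86 ± 0.40), the NF-kappa-B inhibitor nfkbiab (-0.52 ± 0.25) and lgals9l1 (-0.87 ± 0.44), and their median changed sign under both normexp settings (0.27 as planned and 0.0033 without extreme spots, the latter at camera adjusted p = 0.107). With the midbrain and hindbrain covariate the median was -0.11 for endothelial (camera adjusted p = 0.128), -0.11 for oligodendrocyte (0.340) and -0.0094 for inflammation genes (0.773), and with the erythrocyte covariate -0.11 for inflammation genes (0.206).

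Several lists lay higher in High. All 12 tested telencephalon genes were higher, with a median of 0.28 (camera adjusted p = 0.0371; adjusted p = 0.454 with an estimated correlation), among them bhlhe22 (0.33 ± 0.19) and neurod6a (0.28 ± 0.23). The forebrain factor foxg1b, which an outlier spot kept out of the list test, had -0.74 ± 0.42. Heat shock and unfolded protein response genes had a median of 0.16 with 26 of 33 higher (camera adjusted p = 0.0134; adjusted p = 0.454 with an estimated correlation). The call was lost under normexp without extreme spots (0.13, camera adjusted p = 0.137) and with the description number as a block (0.11, 0.110), and the median was -0.21 under the planned normexp that failed. The secreted stress factor manf had 0.47 ± 0.20, and the endoplasmic reticulum genes hsp90b1 0.22 ± 0.12 and sdf2l1 0.28 ± 0.17. Pituitary genes had a median of 0.28 with 6 of 7 higher (camera adjusted p = 0.0463; adjusted p = 0.454 with an estimated correlation), among them the prohormone convertase pcsk1 (0.34 ± 0.27). For lhx3, not well above background on any Control array and above it on 4 of 6 High arrays, High was at least 1.13-fold higher. With the midbrain and hindbrain covariate the telencephalon and pituitary medians stayed at 0.23 and 0.25, both at camera adjusted p = 0.054. With Control 7 and 31 averaged the pituitary median was 0.29 (0.0599). Neither list was particular to High: in Medium against Control the telencephalon and pituitary medians were 0.36 (camera adjusted p = 0.0652) and 0.28 (0.126). In High against Medium they were -0.042 (0.965) and 0.041 (0.874).

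Ribosomal and oxidative phosphorylation genes moved by small amounts. The ribosomal median was 0.053 with 62 of 80 higher (camera adjusted p = 0.0291; adjusted p = 0.928 with an estimated correlation), and the oxidative phosphorylation median 0.052 with 59 of 82 higher (camera adjusted p = 0.0374; adjusted p = 0.928 with an estimated correlation). Under normexp without extreme spots both kept their sign and lost the call, at 0.029 (camera adjusted p = 0.489) and 0.034 (0.458). Both were -0.09 in unscaled values, where the median of all probes was -0.15, and -0.56 under the planned normexp that failed. Quantile normalization took the ribosomal median to 0.0077 (camera adjusted p = 0.647) and that of oxidative phosphorylation to 0.031 (0.128), and ended the inflammation call with its median at -0.26 (0.0820). Members with the smallest p were rps8b (0.26 ± 0.17), rpl30 (0.17 ± 0.12) and rps9 (-0.14 ± 0.09) in the first list, and cox7a1 (0.86 ± 0.25), the succinate dehydrogenase subunit sdhb (0.23 ± 0.12) and the ATP synthase subunit atp5pf (-0.45 ± 0.25) in the second. The erythrocyte covariate left the ribosomal median at 0.030 (camera adjusted p = 0.206) and that of oxidative phosphorylation at 0.027 (0.254), and the midbrain and hindbrain covariate left the latter at 0.025 (0.358).

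No single probe passed the limma test of High against Control (0 of 36640, smallest adjusted p = 0.648), and 1322 had an unadjusted p under 0.05 where chance gives 1832, 448 of them higher. With slide as a block the counts were 0 and 1154. Genes with the smallest p that were higher were git2b (0.80 ± 0.19), the nuclear receptor rorcb (1.41 ± 0.36), the chaperonin subunit tcp1 (0.46 ± 0.12), sacm1lb (0.72 ± 0.19) and the chromatin protein cbx1a (0.60 ± 0.16). Those that were lower were the crystallin cryba1b (-0.95 ± 0.20, above background on 2 of 6 High arrays), taf1b of the RNA polymerase I machinery (-0.99 ± 0.23), asb5b (-1.10 ± 0.26), the sorting nexin snx22 (-1.52 ± 0.37) and pimr166 (-2.11 ± 0.51), a member of a large kinase family whose copies the probe can share. The unadjusted count was 801 without Control 7, 693 without Control 31, 2433 without High 2 and 2645 without Control 11.

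Within slides 1 to 4 and then with slide as a block, the medians of High minus Control were 0.10, -0.23, 0.013, -0.38 and -0.17 for endothelial, -0.16, -0.43, -0.14, -0.097 and -0.25 for oligodendrocyte, 0.91, -0.78, 0.067, -0.46 and -0.24 for inflammation, and 0.024, 0.11, 0.49, 0.12 and 0.18 for telencephalon genes. They were -0.018, 0.045, 0.14, 0.27 and 0.15 for heat shock, 0.79, -0.42, 0.24, 0.49 and 0.24 for pituitary, -0.0085, -0.0014, 0.34, -0.098 and 0.069 for ribosomal and -0.33, 0.18, 0.24, 0.095 and 0.062 for oxidative phosphorylation genes, and the block kept all 8 calls. Leaving out 1 array ended the call for oligodendrocyte genes (Control 7, Control 11 or High 18, adjusted p up to 0.104), heat shock (High 32 or Control 26, up to 0.109), ribosomal (High 2, 13 or 18, Control 16 or 26, up to 0.801), telencephalon (Control 7, 11 or 16, High 12, 18 or 24, up to 0.215), oxidative phosphorylation (Control 11, 16 or 26, High 13, 18, 24 or 32, up to 0.448) and inflammation genes (Control 11, Medium 22, High 12, 13, 18, 24 or 32, up to 0.631). Without Control 16 the ribosomal median was -0.014. The pituitary call was lost on leaving out any of 12 arrays (up to 0.132), that is each array except High 13, Medium 4, Medium 8 and Medium 10, and the endothelial call on leaving out none.

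**Figure D3:**
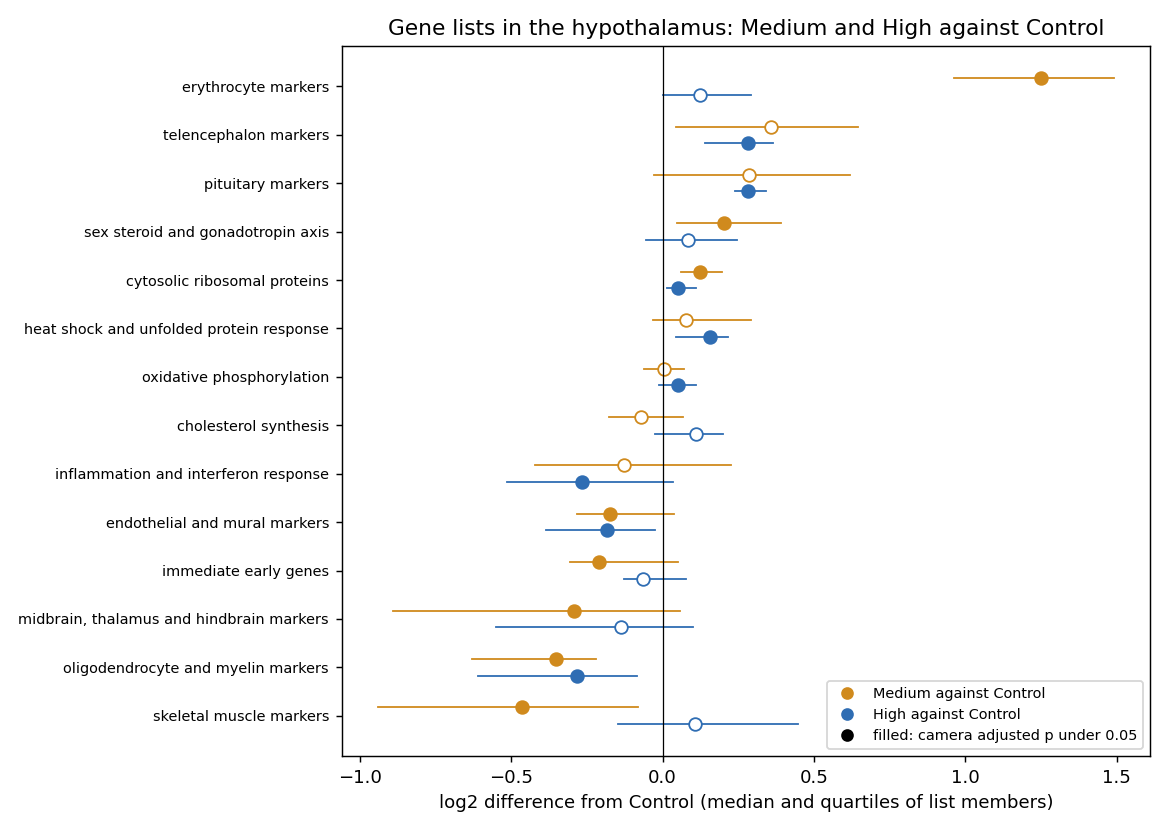
Median (points) and quartiles (lines) of the log2 difference from Control over the members of each gene list called in any comparison, in Medium and High, with filled points where camera gave an adjusted p under 0.05. Erythrocyte genes stand at 1.25 in Medium and 0.12 in High, while ribosomal genes, at 0.12 and 0.053, turn to -0.13 and -0.09 in unscaled values, whose median over all probes is -0.25 and -0.15.

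The comparison of High with Medium tests the differences between the dieldrin feeds themselves. Red cell genes were lower in High than in Medium in all 16 cases, with a median of -1.03 (camera adjusted p = 3.00e-15; adjusted p = 0.276 with an estimated correlation). The globin hbba2 was 11.7-fold lower (-3.55 ± 0.80), at 1.31 ± 1.94 (SD, n = 6) in High. Adjusted over the list alone 10 members passed, 13 with slide as a block and 3 without Medium 33. Clock genes again differed in both directions, with 12 of 27 past the test over the list alone and 10 with slide as a block. The nuclear receptor rorca (1.52 ± 0.31), cry3b (1.06 ± 0.23) and the activator bmal1b (1.32 ± 0.31) were higher in High, and the output factor tefa was lower (-0.74 ± 0.17). The clock list had a median of -0.25 with camera adjusted p = 0.152, and the fry test for change in either direction gave an adjusted p of 0.00542, which was 0.387 with the erythrocyte covariate and 0.0799 in unscaled values. The clock count was 7 without Medium 4 and 6 without High 13 or Medium 33. It was 0 with the erythrocyte covariate, which by itself separates all Medium from all High arrays.

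Skeletal muscle genes were higher in High than in Medium in 22 of 28 cases (median 0.46, camera adjusted p = 7.31e-05; adjusted p = 0.927 with an estimated correlation), cholesterol synthesis genes in 21 of 26 (0.17, 0.00609; adjusted p = 0.958 with an estimated correlation) and immediate early genes in 18 of 22 (0.12, 0.0108; adjusted p = 0.927 with an estimated correlation), the last at -0.025 under the planned normexp background. Oxidative phosphorylation genes were higher in 60 of 82 (0.056, 0.0374; adjusted p = 0.962 with an estimated correlation), but at -0.070 under that background, and their call was lost in unscaled values (0.16, camera adjusted p = 0.159). Ribosomal genes were lower in 70 of 80 (-0.074, 0.00628; adjusted p = 0.962 with an estimated correlation), but at 0.030 in unscaled values (median of all probes 0.098) and 0.060 with the erythrocyte covariate. Under normexp without extreme spots their median was -0.065 and their call was lost (camera adjusted p = 0.159). In High against Control the muscle, cholesterol and immediate early lists were not called, with medians of 0.11 (camera adjusted p = 0.287), 0.11 (0.287) and -0.063 (0.768). In Medium against Control muscle and immediate early genes were called lower, and cholesterol genes were not called (-0.072, camera adjusted p = 0.126). In limma, 0 of 36640 probes passed (smallest adjusted p = 0.488), and 1682 had an unadjusted p under 0.05, 642 of them higher, against 1832 by chance. With slide as a block the counts were 0 and 1666. Other genes with the smallest p were rorcb (1.50 ± 0.36) and arih1l (0.57 ± 0.13), higher in High, and the photolyase relative cry-dash (-1.14 ± 0.25), the platelet integrin itga2b (-1.53 ± 0.34) and igfbp1a (-1.01 ± 0.22), lower in High.

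For High minus Medium, the medians within slides 1 to 4 and with slide as a block were -1.35, -0.59, -0.19, -3.06 and -1.05 for erythrocyte, 0.39, 0.47, 0.34, -0.39 and 0.46 for muscle, -0.35, 0.22, 0.20, 0.44 and 0.17 for cholesterol and 0.14, 0.17, 0.56, -0.38 and 0.093 for immediate early genes. They were -0.011, 0.0072, 0.0015, -0.29 and -0.047 for ribosomal and -0.20, 0.057, 0.043, 0.079 and 0.024 for oxidative phosphorylation genes, whose calls were both lost with the block (camera adjusted p = 0.290). Leaving out 1 array ended the call for cholesterol (Medium 10 or High 18, adjusted p up to 0.134), immediate early (Medium 8, 10 or 22 or High 18, up to 0.224), ribosomal (Medium 4 or 33, High 12 or 32, up to 0.475) and oxidative phosphorylation genes (Medium 8 or 10, High 13, 18 or 32, up to 0.815), and for neither erythrocyte nor muscle genes.

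Genes of the GABA system, on whose receptor dieldrin acts, were not called in any comparison. Of 23 listed GABA-A receptor subunits 7 were measured, with medians of 0.0076 in Medium and -0.0097 in High (camera adjusted p = 0.894 and 0.812). Of 16 listed genes of GABA synthesis, transport and GABA-B receptors 8 were measured, with -0.033 and -0.026 (0.894 and 0.768). The other members of both lists were not assessed. In Medium, the GABA-synthesising enzymes gad1b and gad2 had -0.23 ± 0.18 and 0.72 ± 0.32, the latter with 3 of 8 probes of that sign, and in High -0.08 ± 0.17 and 0.22 ± 0.31, the latter with 4 of 8 probes. The GABA transporter slc6a1b had -0.02 ± 0.13 and -0.09 ± 0.12. Of dopamine genes, th, which makes its precursor, had 0.24 ± 0.27 and 0.15 ± 0.25, with 1 and 2 of 3 probes of that sign and -0.0060 for Medium in unscaled values (median of all probes -0.25), and the transporter slc6a3 had -0.31 ± 0.30 and -0.27 ± 0.29.

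Reproductive and feeding peptides did not pass either. In Medium and High, gnrh3 had 0.07 ± 0.58 and -0.23 ± 0.56, kiss2 0.26 ± 0.34 and 0.02 ± 0.33, oxt 0.98 ± 0.85 and 0.80 ± 0.82, avp 0.57 ± 0.32 and -0.11 ± 0.31, npy -0.22 ± 0.47 and -0.45 ± 0.45, and pomca 0.39 ± 0.39 and 0.05 ± 0.37. In Medium 1 of 2 gnrh3 probes had that sign. In unscaled values gnrh3 in Medium turned to -0.18, and kiss2 and pomca in High to -0.13 and -0.095. The median of all probes was -0.25 in Medium and -0.15 in High in those values. The brain aromatase cyp19a1b, which makes estradiol in radial glia, had 0.30 ± 0.22 and 0.24 ± 0.21, with 2 and 4 of 5 probes of that sign, and the estrogen receptor esr2a -0.25 ± 0.25 and -0.30 ± 0.24.

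The lists below were not called in Medium or High, and each is given with its medians in Medium and High and their camera adjusted p. Glutamate receptors and transport (17 genes) had -0.084 and 0.022 (0.481 and 0.961), dopamine and serotonin (32) 0.011 and 0.024 (0.894 and 0.812), and neurodegeneration-linked genes (24) 0.013 and -0.026 (0.485 and 0.641). The proteasome (45) had -0.0099 and 0.016 (0.475 and 0.961), antioxidant and Nrf2 targets (26) 0.043 and 0.0028 (0.846 and 0.768) and xenobiotic metabolism and transport (16) -0.14 and -0.053 (0.119 and 0.154), with cyp1a at -0.77 ± 0.24 in High. Hypothalamic neuropeptides (31) had 0.16 and -0.0035 (0.219 and 0.768), hypothalamic regional transcription factors (41) 0.16 and 0.052 (0.183 and 0.278) and the glucocorticoid response (14) -0.0067 and -0.027 (0.894 and 0.287), with fkbp5, a chaperone that glucocorticoids induce, at -2.99 ± 0.96 in High against 0.53 ± 2.04 (SD, n = 5) in Control. Microglia and leukocyte genes (25) had -0.047 and -0.24 (0.213 and 0.0536), radial glia and astroglia (19) -0.10 and 0.0098 (0.123 and 0.965), pan-neuronal genes (23) -0.016 and -0.019 (0.192 and 0.768), retina and pineal photoreceptors (16) -0.011 and 0.13 (0.706 and 0.373) and the cell cycle (26) -0.064 and -0.093 (0.192 and 0.238), with dut at 0.36 ± 0.15 and 0.50 ± 0.14. The clock list had 0.096 in Medium (0.894) and the erythrocyte list 0.12 in High (0.228). Median, mean and test differed in sign for lists near 0, in Medium for both GABA lists, dopamine, neurodegeneration, oxidative phosphorylation, antioxidant, glucocorticoid and photoreceptor genes, and in High for GABA synthesis, dopamine, proteasome and antioxidant genes.

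Across the 3 groups, the limma F test gave 0 of 36640 probes past the adjusted threshold (smallest adjusted p = 0.579) and 1595 at an unadjusted p under 0.05. Over the 35251 probes with no outlier spot, the log2 differences of Medium and of High from the same Control arrays correlated across probes, which are not independent replicates, at r = 0.563. Unchanged groups simulated against those controls gave a mean r of 0.508, from 0.0219 to 0.873. The covariance was 0.0671 where the simulation gave 0.0588 on average and 0.183 at most. With the Control arrays divided so that each comparison had its own, r averaged 0.125 over 20 divisions, from -0.0318 to 0.309. At an unadjusted p under 0.05, 100 probes were higher and 208 lower in both comparisons, where independent lists give 14.1 and 21.1, a value that leaves out the shared controls.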

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

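All tests in the paragraphs on red cell and clock genes were chosen after the result was seen, and the share tests that allow for the choice of list were added last. Of 321 groups of values tested for an array far from the rest of its group, 29 held one, and chance gives about 1 in 20.

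The erythrocyte score, the mean level of the list, was higher in Medium than in Control by 1.37 (exact permutation p = 0.00794, 0.0292 after Benjamini-Hochberg over 9 such tests) and lower in High than in Medium by -1.19 (exact permutation p = 0.00216, 0.0195 adjusted), with 0.18 between High and Control (exact permutation p = 0.526, 0.676 adjusted). The adjustment leaves out the choice of this list, which was picked for standing out in the same arrays. These p-values therefore do not exclude a chance difference. Slide is argued against as the cause, since the Medium difference was 1.45 ± 0.41 (SE) with slide as a block and 0.76, 1.16, 1.24 and 2.58 within slides 1 to 4. Blood left in the tissue may account for it: the 16 genes moved together among arrays of 1 group (mean pairwise r = 0.496) and 16 of 16 were higher in Medium, including 6 globin genes whose lowest difference was 0.89. The direction in Medium restates the result, and moving together does not tell blood left in the tissue from an effect of the feed on red cells. Whether the size rests on Medium 33 cannot be told apart, since without it the median was 0.878, above 50% of the full 1.25 by less than the SE of 0.302, and an effect of the feed on red cells stays open and untested. Of 100 splits of the arrays, 1, the real one, gave as many as 11 members past the list-alone test in Medium against Control (10 in the highest other) and 2 as many as 10 in High against Medium (11 in the highest other), but the list had been picked from 31 for standing out, so these counts decide nothing. Allowing for that choice, 1 of 100 splits, the real one, had any list with as large a share of members past the test in Medium against Control (0.69, 0.63 in the highest other) and 2 in High against Medium (0.63, 0.69 in the highest other). Few divisions thus gave such a share. The share tests were added last and leave out the choice among the comparisons, so they do not exclude chance division. In High against Medium the count of 10 was 3 without Medium 33 and 6 with the description number as a block.

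A clock index, the mean of bmal, clock, npas2 and rorca genes minus the mean of per, nr1d and other genes driven through E-boxes, was higher in High than in Control by 1.12 (exact permutation p = 0.013, 0.0292 adjusted) and than in Medium by 1.2 (exact permutation p = 0.0108, 0.0292 adjusted), and differed by -0.073 between Medium and Control (exact permutation p = 0.889, 0.889 adjusted). Here too the adjustment leaves out the choice of the clock list, which was picked for standing out in the same arrays. The p-values of the index therefore do not exclude a chance difference. Slide and the amount of midbrain and hindbrain tissue are argued against as the whole cause, since High minus Control was 0.910 ± 0.27 (SE) with slide as a block, 1.46, 0.19, 0.61 and 1.64 within slides 1 to 4, and 1.16 ± 0.38 with the midbrain and hindbrain score as a covariate. A clock time that differed from sample to sample may account for it: over the 16 arrays the deviations of both arms from their group means opposed each other (Pearson r = -0.657, permutation p = 0.00614; Spearman rho = -0.721, permutation p = 0.00227), and r was -0.814 without the 2 arrays farthest from the median. Opposed arms within groups do not tell a differing clock time from any other change of the clock. They also do not show why High differed from Control. The labels used here do not give the hour of sampling, and an action of dieldrin on the clock stays open and untested. Of 100 splits, 3 gave as many as 9 clock genes in High against Control (12 in the highest other) and 1, the real one, as many as 12 in High against Medium (2 in the highest other), but this list too had been picked for standing out. Allowing for that choice, 12 of 100 splits had any list with as large a share as the clock list in High against Control (0.33, 0.63 in the highest other), so chance division cannot be excluded there, and leaving out any of 5 arrays took the count to 0. In High against Medium 3 splits did (0.44, 0.69 in the highest other). That is few, but the share test leaves out the choice among the comparisons, so chance division is not excluded there either. The count of 12 was 6 without High 13 or Medium 33 and 0 with the erythrocyte covariate, which separates all Medium from all High arrays. The fry test for change in either direction was lost there with that covariate (adjusted p = 0.387) and with the description number as a block (0.0555).

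The arrays that stood apart in a group were these, in log2 signal unless stated. High 18 had 1256 spots marked as outliers, against 19 to 66 on the other High arrays. High 2 had a midbrain and hindbrain score of 1.06, glis3 at -3.70, cyp19a1b at 7.39, snx22 at -1.98, lgals9l1 at 3.31, bhlhe22 at 2.79, foxg1b at -4.36 and neurod6a at 2.73. Medium 33 had slc4a1a at 1.49, gnrhr1 at -2.37, cahz at 4.26, nfkbiab at 4.67, foxg1b at -1.14 and nr1d2a at 2.92. Control 11 had gad2 at 6.88, th at 0.32, cryba1b at -3.76, rps9 at 4.85, nr1d2a at 0.17, fkbp5 at -3.05 and arih1l at -2.55. High 12 had foxo1a at -4.19 and cyp1a at -2.97, High 32 had alas2 at 0.37 and epb41b at 0.11, High 13 had gnrhr1 at -6.13, Medium 10 had pomca at 1.56 and Medium 22 had nr1d1 at -0.44.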

How the results depend on the processing

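The settings added after seeing the data were normexp without spots of extreme local background, Control 7 and 31 averaged, and both covariates. Counts over the list alone were planned for all lists, and the choice to follow those of the erythrocyte and clock lists came after. The erythrocyte list kept its direction in every setting, from 0.88 to 1.50 in Medium against Control and from -1.17 to -0.71 in High against Medium, and its camera call in every setting that used the preset correlation. The planned normexp failed on 6 arrays (High 12, 13 and 18, Medium 10 and 22, Control 16), where 74 spots had a local background over 10 times the array's median. They drew the background mean that normexp fitted down to between -451 and -3080 and flattened those arrays, so its values below show that failure. Counts are given in the order Medium against Control, High against Control and High against Medium where there are 3. At an unadjusted p under 0.05, normexp gave 273, 100 and 70 probes (main 2040, 1322 and 1682) and 1 probe per gene 700, 484 and 621, the latter because fewer probes were tested. Array weights gave 4518 and 4179 for Medium and High against Control, averaging Control 7 and 31 gave 1314 and 698 with 1 array fewer, and Medium against Control had 3543 under normexp without extreme spots and 3465 with the midbrain and hindbrain covariate. The cause of these shifts, including that on averaging Control 7 and 31, was not tested. Of probes past the adjusted threshold, Medium against Control had 2 with only the 2 groups compared (A_15_P664271 and A_15_P663956, unnamed here and chosen after their values were seen) and 0 in the other settings except the replicate block and the fits without 1 array given below. Lists past camera under normexp numbered 14, 14 and 10 (main 8, 8 and 6), and 0, 0 and 0 with an estimated correlation and with fry's directional test. In fry's mixed test, besides the clock list, the erythrocyte list passed in Medium against Control (adjusted p = 0.0214) and High against Medium (0.0311). Lists past camera with the midbrain and hindbrain covariate were 5 and 2 for Medium and High against Control, with the erythrocyte covariate 5 for High against Control and 11 for High against Medium, and with quantile normalization or normexp without extreme spots 5 and 5 for High against Control. Erythrocyte counts over the list alone (main 11 and 10) were 2 and 1 with normexp and 7 and 6 in unscaled values for Medium against Control and High against Medium. Clock counts (main 9 and 12) for High against Control and High against Medium were 0 and 0 with normexp and 5 and 4 in unscaled values, 17 with array weights and 0 with Control 7 and 31 averaged for the former, and 0 with the erythrocyte covariate for the latter. The correlation of Medium and High differences was 0.916 with normexp (main 0.559).

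List medians turned sign under normexp for ribosomal (-0.36 in Medium, -0.56 in High), oxidative phosphorylation (-0.56 in High against Control, -0.070 in High against Medium), heat shock (-0.21), inflammation (0.27) and radial glia (-0.43) in High against Control, endothelial (0.038 in Medium, 0.033 in High), and immediate early (-0.025) and inflammation (0.14) in High against Medium, and the test of dopamine genes in High against Control turned direction with a median of 0.33. Ribosomal genes turned with the erythrocyte covariate (-0.020 in Medium against Control, 0.060 in High against Medium) and without Control 16 (-0.014 in High against Control, where the median was 0.090 without Control 7). Unscaled values ended the camera calls of ribosomal genes (adjusted p = 0.227, 0.674 and 0.455 in the 3 comparisons), muscle genes in Medium against Control (0.306), inflammation (0.205) and oxidative phosphorylation (0.245) in High against Control and the latter in High against Medium (0.159). The planned normexp ended those of endothelial genes (0.571 and 0.413), muscle in Medium (0.578), and telencephalon (0.383), heat shock (0.191) and inflammation genes (0.951) in High against Control, and of immediate early (0.995) and oxidative phosphorylation genes (0.175) in High against Medium. The share of higher probes changed with scaling and with background correction. Unscaled values had 332 higher and 2293 lower, 85 and 1162, and 702 and 486 (main 1157 and 883, 448 and 874, 642 and 1040), and normexp without extreme spots 2975 and 568, 793 and 638, and 413 and 1197.

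Leaving out 1 array gave 0 to 2 probes past the adjusted threshold in Medium against Control, 0 to 0 in High against Control, 0 to 1 in High against Medium and 0 to 1 in the F test. The unadjusted counts ran from 1367 to 3330, 693 to 2645 and 1210 to 2581, the lists past camera from 7 to 13, 2 to 9 and 3 to 10, the erythrocyte counts from 8 to 13 and 3 to 14, the clock counts from 0 to 17 and 6 to 14, and the correlation from 0.452 to 0.673. The adjusted counts above 0 came without High 32 (2), and without Medium 8 (1 and 1). The lists numbered 13 without Medium 4, 2 without High 18 and 3 without Control 11 in High against Control, and 10 without High 24 or Medium 22 in High against Medium.

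The numbers in the sample descriptions, shared by the groups, gave little sign of pairing the arrays. Same-numbered arrays deviated together at a mean r of 0.0283 (other pairs -0.0058), from -0.337 to 0.248, with 4 of 15 over 0.1. So few and variable correlations cannot exclude a pairing. With that replicate block, the fry test of clock genes in either direction had adjusted p = 0.232 in High against Control and 0.0555 in High against Medium (0.554 and 0.922 with normexp), 1 probe passed in Medium against Control (clmnb, adjusted p = 0.0457), 1984 had an unadjusted p under 0.05 in High against Control, 5 lists passed there, and 3 clock genes there and 6 erythrocyte genes in High against Medium passed over the list alone. The calls it ended were heat shock (camera adjusted p = 0.110), inflammation (0.143), oxidative phosphorylation (0.253) and pituitary genes (0.0934) in High against Control, and ribosomal (0.165) and oxidative phosphorylation genes (0.324) in High against Medium. Of 143 differences of genes that the naming rule covers, 45 changed sign in some setting and 1 passed the threshold in some setting. Genes near background, such as clmnb, lhx3 and gnrhr3, are limited by signal over background.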

Other observations

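All tests in the next paragraph were chosen after the result was seen, and the counts over other splits of the arrays were set before they were made. The markers of midbrain, thalamus and hindbrain varied together from array to array within the groups. The score of that list was above 0.6 on Control 7 (0.63), Control 31 (0.63), Control 11 (0.87) and High 2 (1.06), and lowest on Control 26 (-0.54), High 13 (-0.53) and Medium 4 (-0.50). Between groups it differed by -0.47 for Medium minus Control (exact permutation p = 0.190, 0.343 after Benjamini-Hochberg over 9 tests) and -0.29 for High minus Control (exact permutation p = 0.450, 0.675 adjusted). A candidate explanation is that samples held differing amounts of neighbouring brain tissue: the mean pairwise correlation of its 27 genes was 0.199, where the median of 1000 random lists matched on level was 0.0031 and their highest 0.086. Over the fixed lists the same correlation ran from -0.0046 (glucocorticoid response) to 0.57 (ribosomal), with 0.27 for hypothalamic regional transcription factors. Random lists therefore cannot tell differing tissue amounts from other reasons for related genes to vary together. No biological explanation was tested for it.

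Control 7 and Control 31, from slides 1 and 4, were the most similar pair of arrays, with r = 0.990 and 22 of 10707 bright probes differing over 2-fold, where the median pair had 397. They differed in the peptide gene oxt (1.38 and 4.92), and were kept as separate samples. Whether they hold the same or related material is not known. If they do, every p-value against Control rests on fewer independent samples than were counted. With the pair averaged, 1314 probes in Medium and 698 in High against Control had an unadjusted p under 0.05 (2040 and 1322 with both arrays). The next most similar pair crossed the groups: High 2 and Control 11 had r = 0.983 and 46 such probes. Both had the highest midbrain and hindbrain scores (1.06 and 0.87). Without High 2 the unadjusted count of High against Control was 2433 and without Control 11 it was 2645, where all arrays gave 1322.

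Other splits of the arrays into groups of the same sizes, 100 per comparison and over probes with no outlier spot, were compared with the real ones. For probes past the adjusted threshold the real count was 0 in Medium against Control, High against Control, High against Medium and the F test, so that all 100 splits had to reach it and the count decides nothing, with 1, 411, 5 and 1477 in the highest other split. At an unadjusted p under 0.05, 20 splits gave at least 1959 in Medium against Control, 47 at least 1268 in High against Control and 55 at least 1589 in High against Medium, with 5981, 7211 and 6358 in the highest others. For lists past camera, 38, 39 and 67 splits gave at least 8, 8 and 6, with 16, 14 and 16 in the highest others, and for the correlation of Medium and High differences 42 splits gave at least 0.563, with 0.814 in the highest other. Chance division cannot be excluded for the unadjusted counts, the lists and the correlation. Splits with several times the real count point to a structure of the samples, whose source was not tested.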
